A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

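RNA abundance was measured in 8 cultures of haploid budding yeast, Saccharomyces cerevisiae, derived from the laboratory strain W303. Per the labels, the native eIF5A genes HYP2 and ANB1 were disrupted in all strains, which lived on a plasmid-borne human EIF5A1. In 4 strains this was the wild-type protein and in 4 the temperature-sensitive point mutant V81G. Cells were grown at 25 °C, a permissive temperature, to early log phase. Total RNA was extracted with hot phenol, and 6 µg per sample was turned into biotin-labelled cRNA, per the labels' protocols. Each sample was hybridised to 1 Affymetrix yeast array of 9335 probe sets, a 1-colour design in which a probe set summarises several short probes of a transcript. The labels call the arrays of a group biological replicates, and the series design names 4 isogenic strains per group.

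The deposited values were probe-set intensities on a linear scale, between 89.9 and 44207. The submitters' processing notes name RMA, a method that corrects background, brings all arrays to a shared distribution and summarises probes, without a version. No log2 step is recorded in the sources used here, so the linear scale was read from the values, and log2 was taken before every test. Median intensities of the arrays labelled V81G 1 to 4 were 1183, 1168, 1135 and 1141, and those of the arrays labelled wild type 1 to 4 were 1124, 1189, 1100 and 1098. Whether the values were scaled or centred after RMA stays unknown. The highest value of 3 arrays lay within 1 unit of the table's maximum, 15.43 on the log2 scale, so differences of the brightest probe sets may be compressed. No detection calls or saturation marks were used here. For arrays, precision is limited by their number, 4 per group. The lower of the limits used to leave out dim probe sets was 9.03 on the log2 scale. Where a group's mean lay under it, background can shrink a difference. The printed size is then called a lower limit with regard to background only, since noise can move it either way. Besides mitochondrially encoded genes, those with such means include EST2, KAR5, LSM7, MET16, MGE1, PAI3, RRP4, SIP18, SPO16, STE2, STE6, STN1 and URA10. Dimmer probe sets of DAL5 (9.01 in the arrays labelled wild type) and HAC1 (7.88 in those labelled V81G) lay there as well.

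The 60 Affymetrix control probe sets were left out of the tests, which leaves 9275. Gene names came from the platform annotation, updated by gene ID through the RefSeq gene table of assembly R64. A single symbol was found for 6504 probe sets, all of which matched that table. A further 328 had several symbols and stayed unnamed, and 2443 were not listed. Where a gene had more than 1 probe set (315 of 5656 genes), the one with the highest mean over all 8 arrays stood for the gene. Disagreeing probe sets are given beside the gene. The same table gave each gene's chromosome, and its coordinates served only to order genes along the chromosomes.

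Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. All differences are log2 values of V81G minus wild type, so rose and fell mean higher or lower in the arrays labelled V81G. Values are given as mean ± SD over 4 arrays, and differences with their standard error (SE). Adjusted p-values of single genes are limma's. Before the data were examined, 37 gene lists were fixed from general knowledge. They were tested with camera, limma's competitive list test, at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists. Beside it stand camera with a correlation estimated from the arrays and fry, which compares a list with no other genes. Of the fixed members, 25 had no probe set of a single gene. The rules for 3 further lists, of genes with introns, genes near chromosome ends by distance and proteins with proline runs, needed a genome and were not applied. Of the 4 lists defined by a name pattern, the pattern for cytosolic ribosomal proteins also took in RPP1, a subunit of RNase P.

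Genes were named by a rule fixed at the same time. It took the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, 15 genes of eIF5A, nonsense-mediated decay and the strain markers, and up to 2 rises and 2 falls per list. It named 115 genes, of which 107 were called. Members that complete a count of 5 or fewer, and COX3, COB and AI5_ALPHA, were named after their values were seen.

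The run sheets of the arrays gave the hybridization day. In both groups replicates 1 and 2 were hybridised on day 1 and replicates 3 and 4 on day 2, so every result was also fitted with the day as a block and within each day. With the day as a block, group differences stay the same because the days are balanced. The sheets also gave 2 fluidics stations and 1 chip lot, and no pair of arrays held identical values. On day 1 both arrays labelled V81G ran on station 2 and both labelled wild type on station 1. Within day 1 the station therefore cannot be told apart from the group. On day 2 wild type 4 ran on station 2 and the other arrays on station 1. Groups share replicate numbers in the labels, and the deviations of same-numbered arrays from their group means correlated at r = 0.228 to 0.436 in the 4 pairs, above the limit of 0.1 set for pairing. Arrays of the other group from the same day but another number correlated at 0.222 to 0.343, and those from the other day at -0.409 to -0.139. Only 3 of the 8 arrays correlated best with their own number.

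Alternative settings fixed at the same time as the lists were 3 other normalizations between arrays, 2 filters on dim probe sets, the replicate block, the day or station as a block, trend and robust variance, array weights, log2 of the value plus 16, other thresholds, a per-probe-set test with unequal variances, the mean of a gene's probe sets, the estimated correlation, fry, and leaving out each array. Alternatives within each day, without genes of chromosome VIII and with the day block plus estimated correlation were added after the data were seen. RNA quality was judged from 3' and 5' control probe sets with exact permutation tests over the 70 arrangements of 4 against 4 arrays, whose smallest p is 0.0286. On simulated data with 200 changed probe sets among 9275, the limma comparison recovered 29.9% at a 1.5-fold change, 58.2% at a 2-fold change and 97.0% at a 4-fold change. It made 6 false calls among 129. A simulated list shift of 0.5 was called, as were 3 of 100 unshifted lists at an unadjusted threshold of 0.05. Simulated genes varied independently of each other, so these list results do not cover lists whose members vary together.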

Results

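The data describe steady-state RNA in yeast cells that, per the labels, depended on human eIF5A, a translation factor carrying the modified residue hypusine, either as the wild-type protein (4 arrays) or as the temperature-sensitive mutant V81G (4 arrays). All cultures grew at 25 °C, where the mutant strain grows. The comparison asks which transcripts differ between strains of these labels, and no loss of eIF5A function was measured here. Other differences shared by the strains of a group cannot be told apart from an effect of V81G. The series title names transcripts that are targets of nonsense-mediated decay (NMD), the pathway that degrades mRNAs with premature stop codons. Within the group labelled V81G, log2 intensities of arrays from the same hybridization day correlated at r = 0.983 to 0.991 and those from different days at 0.953 to 0.957, across probe sets. Within the group labelled wild type the values were 0.978 to 0.984 and 0.954 to 0.981, and between the groups they were 0.921 to 0.953.

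HYP2 (YEL034W), the main native eIF5A gene, was the first check of the labels, since it is described as disrupted in every strain. Its signal was 15.42 ± 0.01 (SD, n = 4) on the log2 scale in the arrays labelled wild type, next to the highest value of the table, and 12.02 ± 0.23 (n = 4) in the arrays labelled V81G. The difference was -3.41 ± 0.14 (SE), which may be compressed at that ceiling, with a limma adjusted p of 1.1e-06, and it was -3.26 on day 1 and -3.56 on day 2. The level goes against the description of a disrupted gene in the arrays labelled wild type. In those labelled V81G it was also above the median of all probe sets, 10.17. Groups are therefore called by their labels throughout. Whether the probes lie in the disrupted part of the gene is not given in the sources used here. Whether they also read other transcripts in the arrays labelled V81G was not tested. ANB1 (YJR047C), the paralog normally transcribed at low oxygen and also described as disrupted, was bright in both groups, at 14.18 ± 0.20 and 14.04 ± 0.13, and its difference of 0.13 ± 0.14 did not pass the test (adjusted p = 0.595).

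Genes used as selection markers in laboratory yeast strains differed as well. URA3, which encodes the orotidine phosphate decarboxylase of uracil synthesis, fell by 2.33 ± 0.29 on the log2 scale (adjusted p = 5.9e-04), and LEU2, of leucine synthesis, fell by 0.75 ± 0.12 (adjusted p = 0.0030). ADE2, an adenine synthesis gene, rose by 1.39 ± 0.17 (adjusted p = 5.4e-04). The methionine synthesis gene MET17 fell by 2.11 ± 0.33 (adjusted p = 0.0023). TRP1 differed by 0.32 ± 0.25 and did not pass the test (adjusted p = 0.466). The probe sets of HIS3 disagreed, with -1.08 ± 0.39 (adjusted p = 0.0907) for the brighter and -2.56 ± 0.56 (adjusted p = 0.0121) for the other, and the brighter one differed by 0.02 on day 1 and -2.17 on day 2. Of the 8 strain marker genes 1 rose, 3 fell and 4 did not pass, and 2 rose and 5 fell when adjusted over the list alone. As a list they did not pass camera (adjusted p = 0.363).

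**Figure D1:**
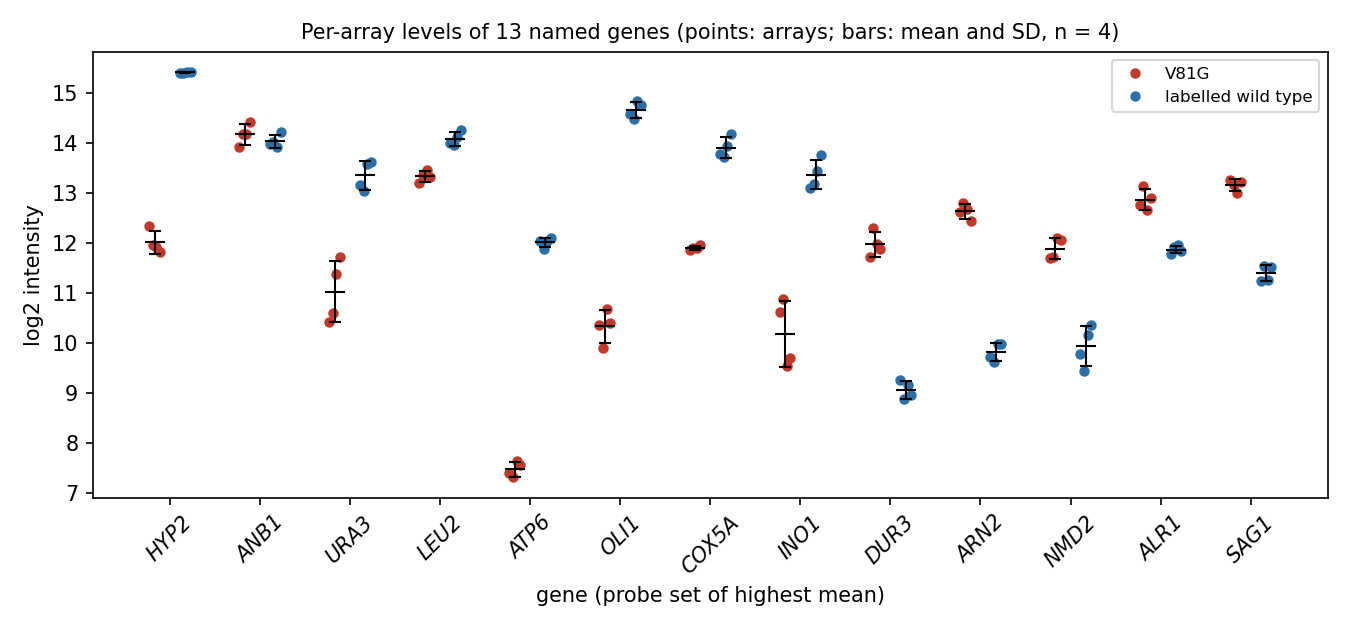
Log2 intensity (vertical axis) of 13 named genes (horizontal axis) in each of the 4 arrays labelled V81G (red points) and the 4 arrays labelled wild type (blue points), with bars for the mean and SD. HYP2 lies at 15.42 in the arrays labelled wild type and at 12.02 in those labelled V81G, while the ANB1 points of both groups overlap.

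Across all 9275 probe sets 1628 passed the test, 831 higher and 797 lower in the arrays labelled V81G. Of these, 497 differed at least 2-fold, 299 upward and 198 downward. Counting 1 probe set per gene, 521 genes rose and 696 fell among 5656. The largest rises were those of DUR3, a urea and polyamine transporter (2.91 ± 0.16, 7.51-fold, adjusted p = 7.7e-06), and ARN2, a transporter of iron-siderophore complexes (2.81 ± 0.14, 7.03-fold, adjusted p = 4.1e-06). They were followed by the maltose transporter genes MAL11 (2.58 ± 0.15) and MAL31 (2.35 ± 0.20), the vacuolar transporter gene VMR1 (2.53 ± 0.17) and YHR210C (2.42 ± 0.20). RRT13 rose by 2.19 ± 0.17, the allantoate transporter gene DAL5 by 2.13 ± 0.13 (1.34 ± 0.22 and 1.19 ± 0.20 in its dimmer probe sets) and THI21, a thiamine synthesis gene, by 2.10 ± 0.18. HXT3, a low-affinity glucose transporter gene, rose by 2.31 ± 0.33, by 3.18 on day 1 and by 1.45 on day 2. With the hybridization day as a block 2389 probe sets passed, including all 1628, and each of the 1628 had the same sign on both days. Because the 1628 were called from both days together, this agreement is not independent support. Day 1 alone gave 1093 probe sets (615 up, 478 down), 868 of them among the 1628. Day 2 alone gave 1845 probe sets (859 up, 986 down), 1148 of them among the 1628.

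Genes of chromosome VIII stood above those of the other chromosomes. The median difference of its 259 measured genes was 0.46, against -0.09 for the 5378 genes of the other nuclear chromosomes, a gap of 0.56 or 1.47-fold. On that chromosome 107 genes rose and 5 fell (ARG4, COX6, GND1, HXT5 and OPI1), and 88.8% had a positive difference. The chromosome's median less that of the other chromosomes, taken in each array relative to every gene's mean in the arrays labelled wild type, was 0.58 ± 0.11 (SD, n = 4) in the arrays labelled V81G and 0.006 ± 0.13 (n = 4) in those labelled wild type (exact permutation p = 0.0286, two-sided, the smallest possible). The value in the arrays labelled wild type is near 0 by construction, since their own means are the reference. Chromosome VIII was singled out after its values were seen, so this p is not independent support. Within days the chromosome's median was 0.51 and 0.50. Of the 10 largest rises, 4 (DUR3, ARN2, VMR1 and YHR210C) are genes of this chromosome, and 1486 probe sets passed when its genes were left out. Members on chromosome VIII are counted beside each list below where any of them rose.

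**Figure D2:**
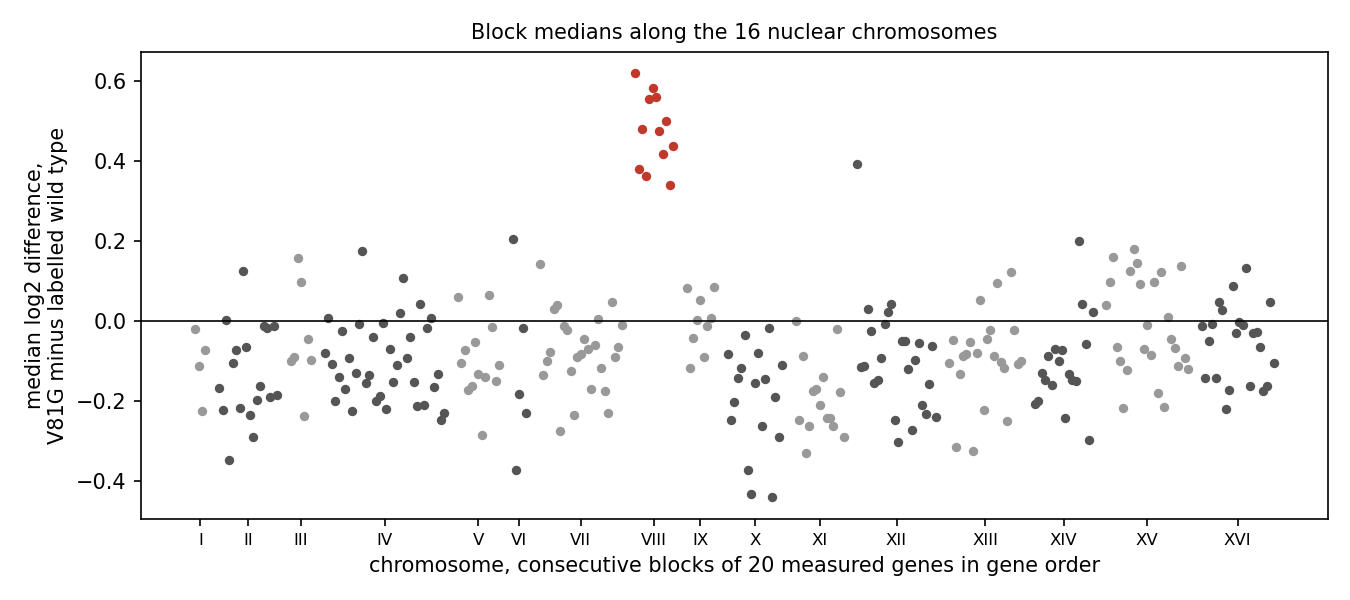
Median log2 difference between the groups (vertical axis, V81G minus wild type as labelled) of consecutive blocks of 20 measured genes in gene order along the 16 nuclear chromosomes (horizontal axis); red points are chromosome VIII, and the alternating greys only separate the other chromosomes. The 12 blocks of chromosome VIII lie between 0.34 and 0.62, and 1 block elsewhere, on chromosome XII at 0.39, reaches that range.

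NMD substrates, a list of 18 genes with known endogenous targets, shifted upward as a group, with a median difference of 0.50 (camera adjusted p = 1.5e-05, and adjusted p = 0.151 with an estimated correlation). In it 6 members rose, none fell and 12 did not pass, while 16 of the 18 differences were positive, and 10 rose when adjusted over the list alone. FRE2, a ferric reductase gene that is also in the iron list, rose by 1.77 ± 0.13 (adjusted p = 4.9e-05), and DAL7, a malate synthase gene that is also in the nitrogen list, by 1.37 ± 0.15 (adjusted p = 3.7e-04). ALR1, a magnesium transporter gene, rose by 1.00 ± 0.14 (adjusted p = 0.0011). The telomere genes STN1 and EST2 rose by 1.08 ± 0.20 and 0.97 ± 0.14, and FZF1, a regulator of sulfite export, by 0.51 ± 0.14. CPA1, a subunit of carbamoyl phosphate synthetase whose mRNA carries an upstream open reading frame, differed by 0.28 ± 0.15 and did not pass (adjusted p = 0.241). PPR1, a regulator of uracil synthesis, differed by 0.51 ± 0.18 (adjusted p = 0.0841), and passed with the day as a block (adjusted p = 0.0247) or the replicate number as a block (adjusted p = 0.0492). The list's median was 0.35 on day 1 and 0.60 on day 2. The member on chromosome VIII did not rise, and without it the median was 0.51 (adjusted p = 7.3e-06).

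**Figure D3:**
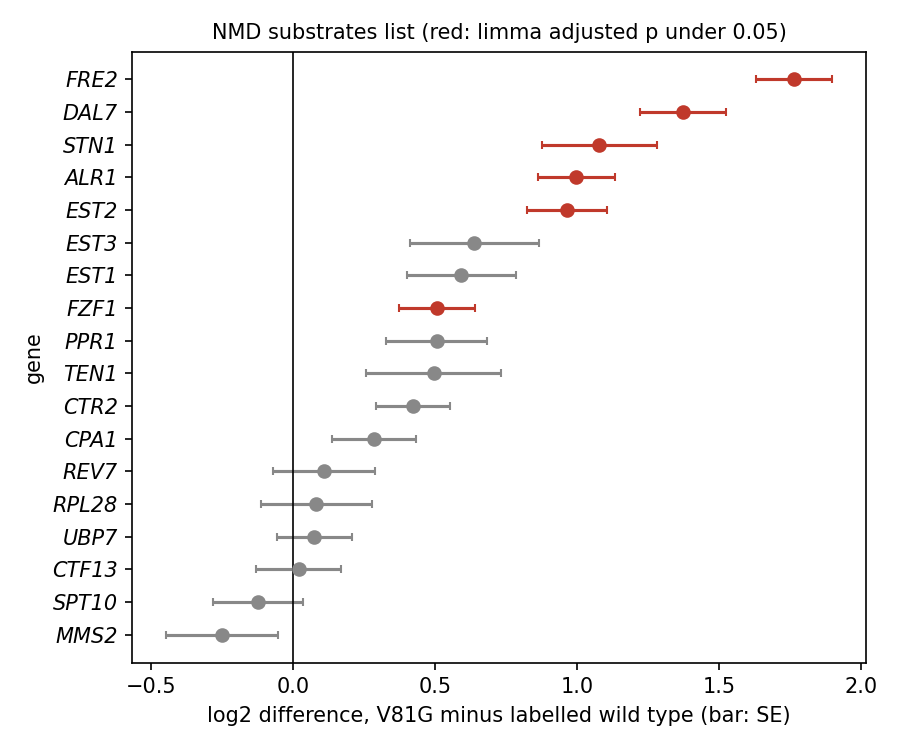
Log2 difference, V81G minus wild type as labelled (horizontal axis), of the 18 NMD substrates (vertical axis), with bars for the SE and red for a limma adjusted p under 0.05. The 6 red genes lie between 0.51 (FZF1) and 1.77 (FRE2), and 2 genes, SPT10 and MMS2, lie below 0.

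Of the 6 NMD factors 2 rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0627), although it passed without V81G 1 (adjusted p = 0.0403) or wild type 4 (adjusted p = 0.0387). NMD2, which encodes the core factor Upf2, rose by 1.95 ± 0.21 (3.88-fold, adjusted p = 2.9e-04) and lies on chromosome VIII, and EBS1, an Est1-like gene, rose by 1.04 ± 0.16 (adjusted p = 0.0020). The helicase gene NAM7 (Upf1) differed by -0.05 ± 0.15 (adjusted p = 0.863) and UPF3 by 0.13 ± 0.19 (adjusted p = 0.703). Among 19 genes with upstream open reading frames 2 rose, also over the list alone, the transporter gene HOL1 (0.92 ± 0.14) and the kinase gene SCH9 (0.68 ± 0.18, on chromosome VIII). This list did not pass (adjusted p = 0.427), with a median of -0.06 below 0 while its mean, 0.05, and its test pointed upward. Decapping and 5'-3' decay genes moved down, with a median of -0.28 (camera adjusted p = 0.0408, adjusted p = 0.298 with an estimated correlation). The ring subunit genes LSM5 (-0.69 ± 0.19), LSM1 (-0.57 ± 0.14) and LSM7 (-0.56 ± 0.15) fell, 14 of 17 members did not pass, and 5 fell when adjusted over the list alone. The call of this list was lost with the replicate number as a block (adjusted p = 0.0510), with the day as a block (adjusted p = 0.0597) and without chromosome VIII (adjusted p = 0.0601), which holds no member, so that the median stayed at -0.28 in all 3, and its medians were -0.22 and -0.35 on the 2 days. Of 23 deadenylation and exosome genes 1 rose and 3 fell, also over the list alone, and the list did not pass (adjusted p = 0.322). The deadenylase genes POP2 (-0.79 ± 0.11) and CCR4 (-0.74 ± 0.15) and SKI8 (-0.72 ± 0.14) fell, and the exosome gene RRP4, on chromosome VIII, rose by at least 0.83 ± 0.19.

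Transcripts of mitochondrial energy metabolism were lower in the arrays labelled V81G. Among nuclear genes of the respiratory chain and ATP synthase 32 of 36 fell and none rose, with a median of -1.29 (camera adjusted p = 4.1e-20, adjusted p = 0.141 with an estimated correlation), and 33 fell when adjusted over the list alone. ATP7, an ATP synthase subunit gene, fell by 2.01 ± 0.16 (adjusted p = 5.1e-05) and COX5A, of cytochrome c oxidase, fell by 2.00 ± 0.13 (adjusted p = 2.9e-05). The list's medians were -1.01 on day 1 and -1.45 on day 2. Of 23 genes of the tricarboxylic acid (TCA) cycle 13 fell and 1 rose, with a median of -0.78 (adjusted p = 0.0012, adjusted p = 0.153 with an estimated correlation), and 14 fell over the list alone. SDH2, of succinate dehydrogenase, fell by 1.76 ± 0.40 and KGD2, of alpha-ketoglutarate dehydrogenase, fell by 1.66 ± 0.30, while the cytosolic malate dehydrogenase gene MDH2 rose by 0.86 ± 0.20. SDH2 and KGD2 differed by -0.83 and -0.89 on day 1 and by -2.68 and -2.44 on day 2, and the list's medians were -0.44 and -1.04. Mitochondrial ribosomal protein genes were lower in 67 of 67 cases, 35 of them past the threshold and 55 when adjusted over the list alone, with a median of -0.61 (camera adjusted p = 1.9e-12, adjusted p = 0.317 with an estimated correlation). MRPL15 fell by 1.34 ± 0.36 and MRPL39 fell by 1.23 ± 0.17, and the medians of the 2 days were -0.88 and -0.37.

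Transcripts encoded by the mitochondrial genome were among the 10 largest falls. ATP6 (Q0085) fell by 4.55 ± 0.12 (adjusted p = 7.7e-08), a lower limit because its signal in the arrays labelled V81G, 7.47 ± 0.14 (n = 4), lay under 9.03, the lower of the limits used to leave out dim probe sets, OLI1 (Q0130), the ring subunit of ATP synthase, fell by 4.33 ± 0.18 (20.1-fold, adjusted p = 1.1e-06) and COX1 (Q0045) fell by 3.44 ± 0.16 (10.9-fold, adjusted p = 2.6e-06). Of 28 such probe sets 7 fell and none rose. The others were the dimmer COX1 probe sets, at -0.96 ± 0.21 and -0.92 ± 0.14, COB (-1.48 ± 0.38) and AI5_ALPHA (-1.06 ± 0.21), whose signals in the arrays labelled V81G lay under 9.03 as well, so these sizes are lower limits too. A dim probe set of OLI1 differed by 0.16 ± 0.18. The other COB probe set differed by -0.78 ± 0.26 without passing (adjusted p = 0.0725). It passed with the day (adjusted p = 0.0059) or the replicate number (adjusted p = 0.0119) as a block. COX3 remained bright in the arrays labelled V81G, at 11.55 ± 0.93 (n = 4), and differed by 1.12 ± 0.41 without passing the test (adjusted p = 0.0956), and passed with the day (adjusted p = 0.0022) or the replicate number (adjusted p = 0.0105) as a block.

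Of 38 genes regulated by Gcn4, the general activator of amino acid synthesis, 22 fell and none rose, with a median of -0.66 (camera adjusted p = 1.1e-07, adjusted p = 0.433 with an estimated correlation), and 27 fell when adjusted over the list alone. HIS4, of histidine synthesis, fell by 1.70 ± 0.19 (adjusted p = 4.1e-04) and MET6, methionine synthase, fell by 1.60 ± 0.31 (adjusted p = 0.0068), and the day medians were -0.61 and -0.68. In arginine synthesis 4 of 7 genes fell and 5 did so over the list alone, with a median of -1.09 (adjusted p = 0.0109, adjusted p = 0.339 with an estimated correlation). The fallen genes were ARG1 (-2.08 ± 0.33), ARG7 (-1.67 ± 0.16), ARG3 (-1.54 ± 0.27) and ARG4 (-1.09 ± 0.13). Day medians were -1.02 and -1.17, and the list lost its call without its member on chromosome VIII, ARG4 (adjusted p = 0.0517), with a median of -0.99 over the other 6.

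Sulfur and methionine genes went both ways, with 3 up and 6 down of 21, 3 and 8 when adjusted over the list alone, and no call as a list (adjusted p = 0.231). SAM2, an S-adenosylmethionine synthetase gene, fell by 2.74 ± 0.22 (6.68-fold), while MET1, of siroheme synthesis, and the sulfite reductase gene MET10 rose by 1.40 ± 0.18 and 0.73 ± 0.14, as did MET16 (0.43 ± 0.12). Nitrogen catabolite genes were as mixed, with 4 up (DUR3, DAL5, DAL7 and DAL2) and 6 down of 22, and 6 and 8 over the list alone. Its median, -0.08, was below 0, its mean, 0.06, above it, and the list did not pass (adjusted p = 0.806). The proline permease gene PUT4 fell by 1.78 ± 0.19 and the ammonium transporter gene MEP1 fell by 1.20 ± 0.17. DUR3 is the member on chromosome VIII that rose. In pyrimidine synthesis URA10 (at least 0.74 ± 0.16) alone rose among 11 genes, also over the list alone, and the list did not pass (adjusted p = 0.202).

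Iron uptake genes were higher. In the iron regulon 14 of 29 genes rose and 1 fell, with a median of 0.62 (camera adjusted p = 2.2e-07, adjusted p = 0.106 with an estimated correlation), and 15 rose and 3 fell when adjusted over the list alone. The siderophore transporter genes ARN2 and ARN1 rose by 2.81 ± 0.14 and 2.05 ± 0.12 and lie on chromosome VIII. Without them the median was 0.51 (adjusted p = 1.9e-06), and the day medians of the whole list were 0.56 and 0.52. ATX1, a copper chaperone gene, fell by 0.41 ± 0.12 (adjusted p = 0.0467), a call lost with the replicate number as a block (adjusted p = 0.0706). Of 13 phosphate regulon genes PHO5 (-0.73 ± 0.15), VTC4 (-0.73 ± 0.13) and VTC1 (-0.70 ± 0.17) fell, and PHO89 rose by 0.40 ± 0.12 (adjusted p = 0.0489, and adjusted p = 0.0773 with the replicate number as a block). The counts were the same over the list alone, and the list did not pass (adjusted p = 0.179).

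**Figure D4:**
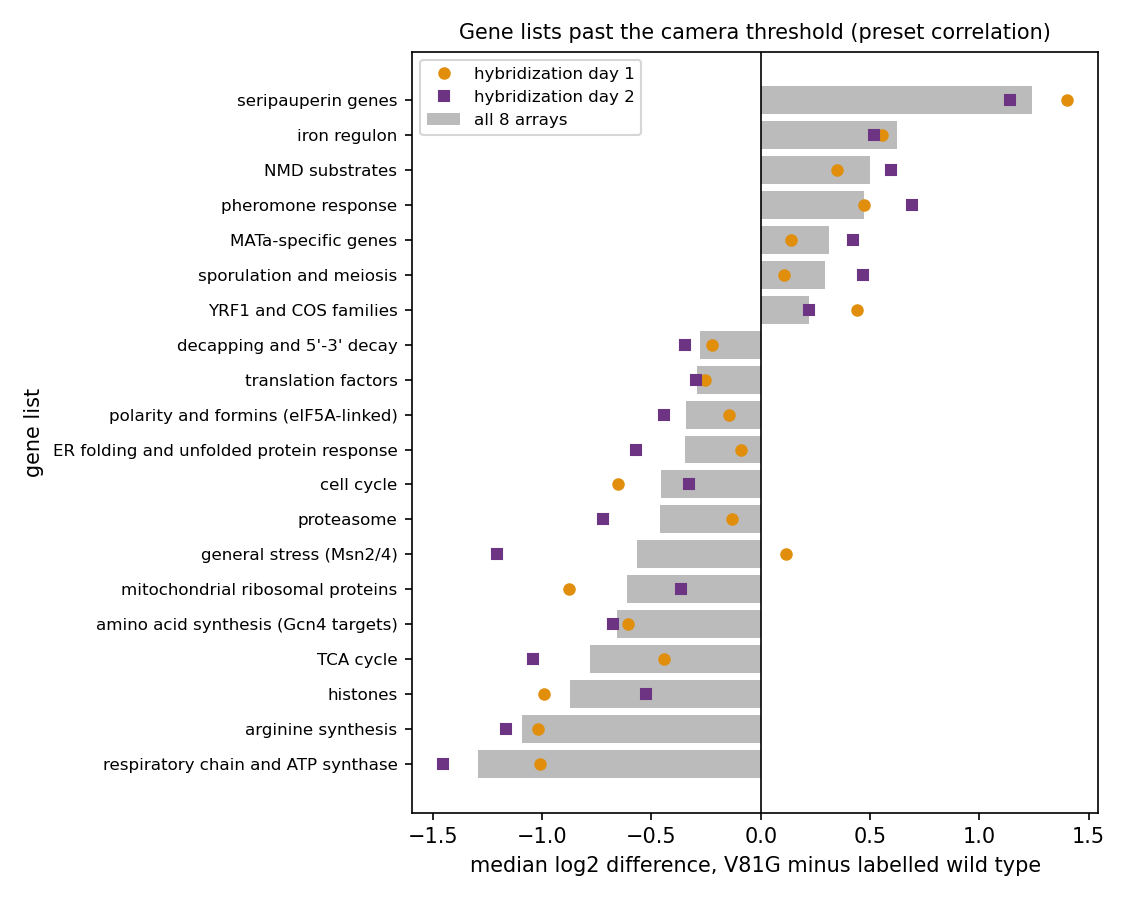
Median log2 difference, V81G minus wild type as labelled (horizontal axis), of the 20 gene lists past the camera threshold at the preset correlation (vertical axis); grey bars use all 8 arrays, orange circles the 4 arrays of day 1 and purple squares the 4 arrays of day 2. The day values share the sign of the bar in 19 lists, and the general stress list lies at 0.11 on day 1 and -1.21 on day 2.

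Seripauperin genes, a family of cell wall mannoproteins induced at low oxygen, rose in 10 of 10 measured cases, also when adjusted over the list alone, with a median of 1.24 (camera adjusted p = 1.3e-10, adjusted p = 0.151 with an estimated correlation). PAU15 rose by 1.93 ± 0.19 and PAU3 by 1.71 ± 0.21. The list's medians were 1.40 on day 1 and 1.14 on day 2, and 1 of the risen members lies on chromosome VIII. Their probe sets are shared between near-identical family members, so the levels of single genes are uncertain. The list of YRF1 helicases and COS genes was measured only through 8 COS genes, which has the same limit. COS8, on chromosome VIII, rose by 0.92 ± 0.15 and COS4 by 0.85 ± 0.19, and 3 rose over the list alone. Its median was 0.22 (adjusted p = 0.0295, adjusted p = 0.298 with an estimated correlation), the day medians were 0.44 and 0.22, and the call was lost without chromosome VIII (median 0.072, adjusted p = 0.0685). Without V81G 4 the median was 0.35.

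Cell wall and cell integrity genes changed in both directions, 5 up and 4 down of 49, also over the list alone, and the list did not pass (adjusted p = 0.883), with a median of -0.02 and a mean of -0.03 beside a test that pointed upward. The mannoprotein gene TIR4 rose by 1.61 ± 0.19, the cell integrity kinase gene SLT2, on chromosome VIII, by 1.22 ± 0.18, its target regulator RLM1 by 0.94 ± 0.22, KDX1 by 0.70 ± 0.18 and TIR2 by 0.46 ± 0.11. The wall protein genes CWP1 (-1.10 ± 0.14) and PIR1 (-1.10 ± 0.13) fell, as did GAS3 (-0.84 ± 0.12) and PST1 (-0.80 ± 0.16). HPF1, another mannoprotein gene and 1 of the 10 largest falls, fell by 2.31 ± 0.16 (adjusted p = 3.1e-05).

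In the pheromone response 10 of 20 genes rose and none fell, with a median of 0.47 (camera adjusted p = 1.0e-05, adjusted p = 0.141 with an estimated correlation), and 11 rose when adjusted over the list alone. KAR5, needed for nuclear fusion, rose by 1.23 ± 0.15, and SST2, a regulator that dampens pheromone signalling, by 1.06 ± 0.16. Day medians were 0.47 and 0.69, 2 of the risen members lie on chromosome VIII, and the median without that chromosome was 0.39 (adjusted p = 1.9e-05). Of 7 genes specific to MATa cells STE2, the alpha-factor receptor gene, rose by 1.14 ± 0.13 and STE6, the a-factor exporter gene, by 0.61 ± 0.17, the same count over the list alone. The other 5 had positive differences too, and the median was 0.31 (adjusted p = 0.0150, adjusted p = 0.393 with an estimated correlation), 0.14 on day 1 and 0.42 on day 2. Without wild type 4 the median was 0.18 and the list lost its call. Among 4 genes specific to MATalpha cells SAG1, the alpha-agglutinin gene, rose by 1.77 ± 0.13 (3.41-fold, adjusted p = 4.3e-05), also over the list alone, and that list did not pass (adjusted p = 0.135). SAG1 lay at 13.17 ± 0.11 in the arrays labelled V81G and at 11.40 ± 0.16 in those labelled wild type. Sporulation and meiosis genes, markers of diploid cells, rose in 9 of 30 cases and fell in none, with a median of 0.29 (adjusted p = 2.2e-05, adjusted p = 0.317 with an estimated correlation), and 11 rose over the list alone. SPS100 (1.22 ± 0.21) and SPO16 (0.77 ± 0.16) are the 2 risen members on chromosome VIII. Day medians were 0.11 and 0.47.

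Cell cycle genes fell in 12 of 34 cases and rose in none, with a median of -0.46 (camera adjusted p = 2.2e-05, adjusted p = 0.298 with an estimated correlation), and 17 fell when adjusted over the list alone. EGT2, a gene of cell separation after division, fell by 2.06 ± 0.31 and DSE4, another, fell by 2.00 ± 0.35, and DSE4 differed by -2.81 on day 1 and -1.19 on day 2. The list's day medians were -0.65 and -0.33. Of the 4 histone genes with a probe set of their own HTB1 (-0.88 ± 0.22), HTZ1 (-0.86 ± 0.16) and HHO1 (-0.56 ± 0.11) fell, and 4 fell over the list alone. The histone median was -0.87 (adjusted p = 0.0136, adjusted p = 0.298 with an estimated correlation), -0.99 on day 1 and -0.52 on day 2. Polarity and formin genes, chosen because eIF5A has been tied to cell polarity, had a median of -0.34 (adjusted p = 0.0396, adjusted p = 0.656 with an estimated correlation). Of these 22 genes 2 fell and none rose, also over the list alone, among them the actin-binding protein gene ABP1 (-0.56 ± 0.13). Day medians were -0.15 and -0.44, and without chromosome VIII, which holds no member, the adjusted p was 0.0601. The call of the polarity list was also lost in 4 of the 8 fits that left out 1 array.

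Translation factor genes had a median of -0.29, on day 1 -0.26 and on day 2 -0.30 (camera adjusted p = 0.0072, adjusted p = 0.656 with an estimated correlation). Of 37 members 35 had negative differences, CAF20, a repressor that binds the cap-binding protein (-0.69 ± 0.14), TIF34 (-0.54 ± 0.16) and SUI2 (-0.52 ± 0.14) fell, and 1 fell when adjusted over the list alone. Among 81 cytosolic ribosomal protein genes 3 rose and 4 fell, 3 and 2 over the list alone, and the list did not pass (adjusted p = 0.0627), although it passed without chromosome VIII (adjusted p = 0.0477) and in 3 of the 8 fits that left out 1 array (lowest adjusted p = 0.0094). RPL7B rose by 1.18 ± 0.19 and RPL22B by 0.98 ± 0.19, while RPS22B (-1.85 ± 0.20), RPL9B (-1.20 ± 0.20), RPL39 (-0.59 ± 0.16) and RPS7B (-0.50 ± 0.14) fell. These are members of near-identical pairs in part, and the remaining gene that rose, RPP1 (1.23 ± 0.14, on chromosome VIII), encodes a subunit of RNase P rather than of the ribosome. Of 84 ribosome biogenesis genes 82 did not pass, none passed over the list alone, and neither did the list (adjusted p = 0.291). Its median of -0.22 was -0.34 without V81G 3 and -0.36 without V81G 4, where the list passed (adjusted p = 0.0094 and 0.0249), but -0.080 without V81G 1 and -0.094 without V81G 2. With array weights the median turned to 0.090, and the list passed camera (adjusted p = 0.0345). DBP8, an RNA helicase gene on chromosome VIII, rose by 0.86 ± 0.24, and the nucleolar protein gene NOP56 fell by 0.72 ± 0.22 (adjusted p = 0.0463, and adjusted p = 0.0628 with the replicate number as a block).

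Lists of protein folding and degradation genes had lower medians on day 2 than on day 1, a difference that was tested only gene by gene. In limma's interaction test 1 of 34 proteasome genes passed, 0 of 29 genes of folding in the endoplasmic reticulum (ER) and 3 of 31 chaperone genes (13, 12 and 17 at an unadjusted threshold of 0.05). Proteasome genes had a median of -0.46, with 9 of 34 down and none up (camera adjusted p = 0.0059, adjusted p = 0.719 with an estimated correlation), and 17 fell and 1 rose when adjusted over the list alone. RPN11, of the lid, fell by 0.86 ± 0.18 and PRE9, of the core, fell by 0.82 ± 0.21, and the list's medians were -0.13 on day 1 and -0.72 on day 2. ER folding and unfolded protein response genes had a median of -0.35, with 7 down and 1 up of 29 (adjusted p = 0.0182, adjusted p = 0.656 with an estimated correlation), 9 and 1 over the list alone, and day medians of -0.09 and -0.57. HAC1, the transcription factor of that response, fell by 0.73 ± 0.14, although 1 dim probe set of it differed by only -0.003 ± 0.13 and another by -1.07 ± 0.36 without passing (adjusted p = 0.0679). The chaperone gene LHS1 fell by 0.71 ± 0.21 (adjusted p = 0.0412, and adjusted p = 0.0558 with the replicate number as a block), and IRE1, the sensor of the response, on chromosome VIII, rose by 0.65 ± 0.15. Of 31 chaperone and heat shock genes SSA3 rose by 0.98 ± 0.12 and CPR3, SBA1, MGE1, SSC1 and HSP10 fell (-0.98 ± 0.15, -0.94 ± 0.14, -0.93 ± 0.15, -0.82 ± 0.19 and -0.66 ± 0.14). Over the list alone 6 fell and 1 rose, and the list did not pass (adjusted p = 0.181), with day medians of 0.006 and -0.51.

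General stress genes, targets of the activators Msn2 and Msn4, differed by day. Their median was -0.57 over all arrays (camera adjusted p = 0.0126, adjusted p = 0.781 with an estimated correlation), but 0.11 on day 1 and -1.21 on day 2. Without V81G 4 it was -0.25, and the call was lost in 2 of the 8 fits that left out 1 array. Of 43 genes YGP1 (-0.96 ± 0.12), UGA1 (-0.81 ± 0.22), PAI3 (-0.72 ± 0.20) and SIP18 (-0.57 ± 0.17) fell, and 1 fell when adjusted over the list alone. The call of UGA1 (adjusted p = 0.0333) was lost with the replicate number as a block (adjusted p = 0.0535). In 18 of the 43 genes the difference between the groups itself differed between days past an adjusted p of 0.05 in limma's interaction test.

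In the list of eIF5A, hypusination and polyamine genes 2 of 15 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.959), with a median of -0.12 and a mean of -0.16 beside a test that pointed upward. DYS1, deoxyhypusine synthase, on chromosome VIII, rose by 0.79 ± 0.22 (adjusted p = 0.0363), and the polyamine exporter gene TPO4 by 0.98 ± 0.24. Of the 8 fits that left out 1 array, 5 ended the call of DYS1 and 4 that of TPO4. LIA1, deoxyhypusine hydroxylase, differed by -0.47 ± 0.20 (adjusted p = 0.152), and passed with the replicate number as a block (adjusted p = 0.0416) or the day as a block (adjusted p = 0.0149). Glycolysis and fermentation genes changed in both directions, 3 up (HXT3, PDC5 at 1.83 ± 0.13 and HXT4 at 1.63 ± 0.48, on chromosome VIII) and 3 down (TDH1 at -1.18 ± 0.20, HXT5 at -0.77 ± 0.23 and PGI1 at -0.46 ± 0.12) of 26, and 4 each over the list alone. The list did not pass (adjusted p = 0.959), its median of -0.07 being below 0 and its mean of 0.08 above. HXT5 lost its call with the replicate number as a block (adjusted p = 0.0561).

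Of 27 ergosterol synthesis genes ERG7, lanosterol synthase (1.12 ± 0.24), and NCP1 (0.58 ± 0.15) rose, both on chromosome VIII. ERG20 (-0.88 ± 0.15), MVD1 (-0.59 ± 0.16), ERG13 (-0.58 ± 0.14) and IDI1 (-0.53 ± 0.15) fell. Over the list alone 2 rose and 5 fell, and the list did not pass (adjusted p = 0.521). Among 15 DNA repair and damage response genes the ribonucleotide reductase genes RNR2 (-0.92 ± 0.13) and RNR4 (-0.82 ± 0.18) fell, as did RAD23 (-0.60 ± 0.16) and UBC13 (-0.47 ± 0.12), while RNR3 (0.55 ± 0.16) and RAD54 (0.49 ± 0.14) rose. The counts were the same over the list alone, RNR3 and RAD54 lost their calls with the replicate number as a block (adjusted p = 0.05001 and 0.0561), and the list did not pass (adjusted p = 0.959), with a median of 0.007 and a mean of -0.08. INO1, the inositol phosphate synthase gene, and OPI3, of phosphatidylcholine synthesis, were among the 10 largest falls of all genes, at -3.19 ± 0.30 (adjusted p = 1.6e-04) and -2.42 ± 0.32 (adjusted p = 8.1e-04). INO1 differed by -2.39 on day 1 and -3.98 on day 2.

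Over the 37 lists 20 passed camera at the preset correlation, 7 upward and 13 downward. With an estimated correlation none passed after adjustment, and 6 had an unadjusted p under 0.05 in camera. RNA quality was compared through the difference between 3' and 5' control probe sets, which grows when RNA is degraded or copied incompletely. Its mean over ACT1, SPT15 and SRB4 was 1.45 ± 0.12 (n = 4) in the arrays labelled V81G and 1.38 ± 0.10 (n = 4) in those labelled wild type (exact permutation p = 0.314, two-sided). ACT1, the actin gene, differed by 0.41 (exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.0857 over the 3 controls). Its 3' probe set lay at 15.17 in the arrays labelled V81G and 15.30 in those labelled wild type. This is near the highest value of all arrays, so its difference of -0.13 may be compressed. The 5' and middle probe sets differed by -0.54 and -0.51. The ACT1 value therefore cannot tell poorer RNA from a lower ACT1 signal. The 5' probe set of SRB4 was dim in both groups (8.59 and 8.50), where background can shrink a difference.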

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

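The tests of HYP2 and of the mitochondrial genome, and those of extra copies and of the day for chromosome VIII, were chosen after the results were seen, and the test of signal-dependent bias was set before its result was known.

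HYP2, described as disrupted in every strain, differed by -3.41 ± 0.14, lower in the arrays labelled V81G, at 12.02 against 15.42. Transcripts of ANB1 read by the HYP2 probe set are argued against as the source of this difference by ANB1 itself, which differed by 0.13 ± 0.14. Whether they add to the HYP2 level of 12.02 in the arrays labelled V81G was not tested. Strains that differ from their description and probes outside the disrupted part of the gene stay open. An effect of the V81G protein on a remaining HYP2 transcript, the biological difference that the design names, was not tested.

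Of 4 mitochondrially encoded probe sets that were bright in the arrays labelled wild type, ATP6, OLI1 and COX1 fell and COX3 differed by 1.12 ± 0.41, which passed with the day as a block (adjusted p = 0.0022). The median of the 4 was -4.02 on day 1 and -3.75 on day 2, so neither hybridization day alone carried the fall. A shift between days could not give it, because the groups are balanced over the days. A lower yield of RNA without poly(A) tails is argued against by other such RNA bright in the arrays labelled wild type, 19 snoRNA probe sets with a median of -0.041 and a lowest value of -1.63 (4 fell, 1 rose), and 53 tRNA probe sets with a median of 0.24, while ribosomal RNA controls were mostly too dim to count and 1 of 10 fell (-0.73). Loss of all mitochondrial DNA in the V81G strains may account for the falls. However, 1 probe set, COX3, stayed bright in all 4 arrays labelled V81G and could read another transcript. OLI1 and COX1 lay at 10.34 ± 0.33 and 10.22 ± 0.15 there, near the limit of 10.17 for bright probe sets. Only in V81G 2 (9.89 and 10.03) were they below it, so they did not count as bright in all 4. Whether all mitochondrial DNA was lost stays undecided under a rule chosen after the values were seen. An effect of V81G on mitochondrial transcripts without loss of DNA was not tested.

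Chromosome VIII had a median of 0.46 against -0.09 for the other nuclear chromosomes, and 100% of its 12 blocks of 20 genes lay above the 95th percentile of the other blocks (0.12). The gap between its median and the highest other chromosome was at least 0.47 within each day, so neither day alone carried it. A shift between days could not give it, because the groups are balanced over the days. Signal-dependent bias of the normalization is argued against by 10000 random lists of other genes matched on mean level, whose highest median was -0.021. Extra copies of chromosome VIII in the V81G strains are a candidate explanation that these values leave open. The gap of 1.47-fold is below the copy ratio of a duplicated chromosome in a haploid cell. Background can shrink array ratios, and the ratio expected on these arrays was not measured, so the size of the gap does not decide. DNA content was not measured, and an effect of V81G on these genes without extra copies was not tested.

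In 12 of the 240 groups of 4 arrays examined, 1 array lay far from the other 3, and chance gives about 1 in 20. On the log2 scale these were ARN1 at 13.07 and SCH9 at 11.17 in the array labelled V81G 1, and ATP7 at 9.79 and VTC4 at 12.26 in V81G 2. Among arrays labelled wild type they were TRP1 at 11.47 in replicate 1, FRE2 at 9.59 and MET6 at 12.41 in replicate 2, CPR3 at 13.75 and CWP1 at 14.38 in replicate 3, and NOP56 at 12.09 and RPS22B at 14.68 in replicate 4. The ACT1 difference between 3' and 5' control probe sets was 1.17 in V81G 4.

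The difference between the groups itself differed between the days in 117 probe sets by limma's interaction test (1375 at an unadjusted p under 0.05), more negative on day 2 in 101 and more positive in 16. HSP30, a plasma membrane heat shock gene, differed by 1.94 on day 1 and -1.96 on day 2, the glucokinase gene GLK1 by 0.02 and -2.50, and TPS1, of trehalose synthesis, by 0.56 and -1.91. Among the named genes these were DSE4, HIS3, HXT3, INO1, KGD2 and SDH2. Each day held other replicates, so the day and the replicate strains cannot be told apart.

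Of the 60 control probe sets, which were left out of the tests of all probe sets, 5 differed between the groups in limma. They were 1 segment of 25S ribosomal RNA (-0.73 ± 0.18), URA3 (-2.64 ± 0.25), RIP1, of the respiratory chain (-1.32 ± 0.18), and the 5' (-0.54 ± 0.15) and middle (-0.51 ± 0.16) segments of the actin gene.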

How the results depend on the processing

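The tests within days, without genes of chromosome VIII and with the day block plus estimated correlation were chosen after the data were seen, and the cause was not tested for any value here that moved, except where it is named.

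Counts of probe sets rested on the threshold and the variance model. Against 1628 probe sets (831 up, 797 down), 804 (469 up, 335 down) passed at an adjusted p under 0.01, 497 (299 up, 198 down) were also changed at least 2-fold, and 837 (442 up, 395 down) passed in a per-probe-set test with unequal variances. Weights estimated per array, from 0.458 (V81G 2) to 2.60 (V81G 4), gave 2614 (1307 in each direction), 1570 of them shared. With the day as a block 1210 fell, because a difference between days no longer adds to the error, and on day 1 alone 478. Leaving out 1 array gave 1131 to 1555, with 613 to 787 up and 500 (without wild type 4) to 768 (without wild type 2) down, and 518 down without wild type 1. Fewer arrays lower these counts by construction. With the replicate block 1858 passed (948 up, 910 down), 1527 of them shared, and 19 lists, without decapping. The replicate block also ended the calls of ATX1, HXT5, LHS1, NOP56, PHO89, RAD54, RNR3 and UGA1 and added LIA1 and PPR1. The 3 other normalizations, both filters and the remaining settings gave counts within 1.5 times, with 46.1 to 54.2% of calls upward over the normalizations. In none of the settings compared probe set by probe set did a shared call turn sign.

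The NMD substrates moved up in every setting run. Their median was 0.46 to 0.51 with adjusted p 2.7e-06 to 6.5e-04 under the 13 settings fixed beforehand with the preset correlation or fry. It was 0.41 to 0.55 (p up to 1.2e-04) without single arrays and 0.35 to 0.60 (p up to 0.0023) under the 3 added ones. With an estimated correlation the median of 0.50 had an adjusted p of 0.151, and 0.134 with the day block, so the call ended. The same settings left 0 of 37 gene lists called by camera, with 6 at an unadjusted p under 0.05 without the block. Because the preset correlation is small, list calls rest on it.

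List counts were 18 to 21 without single arrays and 12 without the probe sets below the median level, where fewer members are tested. The lists lost there were decapping, ER folding, polarity, translation factors, general stress, proteasome, sporulation and MATa-specific genes. Day 1 alone gave 15 lists, day 2 alone 22 and array weights 24. Several downward calls lay near the threshold. Repeated quantile normalization and cyclic loess ended those of decapping, ER folding and polarity genes, and loess that of translation factors. Without V81G 3 or V81G 4 the general stress list lost its call, at -0.32 and -0.25, as did decapping (-0.26 and -0.34) and polarity (-0.24 and -0.28). Polarity also lost it without wild type 1 (-0.30) or 2 (-0.32), the ER list without V81G 4 (-0.23), and MATa-specific genes without wild type 4 (0.18). The stress list had a median of 0.11 on day 1, reversed, and ribosome biogenesis had 0.090 under array weights (adjusted p = 0.0345), against -0.22. Lists without a call passed in some settings. Without single arrays these were NMD factors (median 0.29 without V81G 1, 0.24 without wild type 4), chaperones (-0.33 without V81G 2), ribosomal proteins (-0.21 without V81G 3, -0.18 without V81G 4 or wild type 2) and ribosome biogenesis (-0.34 without V81G 3, -0.36 without V81G 4). The glycolysis median, not called, was 0.11 under loess. None of the 107 called named genes changed sign, and 84 of them were called under every setting fixed beforehand. Of 920 values of named genes without single arrays, 119 lost their call and 1 gained one. CPA1 passed after repeated quantile normalization (0.47) and loess (0.44).

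RNA quality gave 0.41 for ACT1, -0.028 for SPT15 and -0.17 for SRB4 taken alone, with the limits given above for ACT1 and SRB4. Signal over background limits the dim probe sets, and those below the median level of 10.17 on the log2 scale were the dimmer ones left out above. No detection calls were used to tell them from background.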

Other observations

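The tests of the 4 gene groups added here were chosen after the results were seen, while the comparison with other groupings of the arrays was planned.

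Genes of inositol, phospholipid and fatty acid synthesis were looked at because INO1 and OPI3 were among the 10 largest falls. Of 17 measured genes 13 fell and none rose, with a median of -1.21 and day medians of -1.07 and -0.82. INO1, the inositol phosphate synthase gene, gave the largest fall among them (-3.19 ± 0.30), followed by OPI3 (-2.42 ± 0.32) and CHO1 (-1.86 ± 0.16), of phospholipid synthesis, and the inositol transporter gene ITR1 (-1.41 ± 0.17). The fatty acid synthase genes FAS2 (-1.34 ± 0.31) and FAS1 (-1.28 ± 0.27) and the acetyl-CoA carboxylase gene ACC1 (-1.18 ± 0.29) fell too. INO2 and INO4, which encode the activators of these genes, differed by -0.03 ± 0.13 and 0.17 ± 0.16 and did not pass. Their repressor gene OPI1 fell by 0.55 ± 0.14 and lies on chromosome VIII. Members were picked in part because their fall had been seen, so a list test on these arrays decides nothing about the group.

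Genes near chromosome ends were higher. The measured genes among the 10 outermost protein-coding genes of each end, without chromosome VIII, had a median of 0.20 (190 genes, 59 up and 13 down), against -0.10 for genes elsewhere, and the highest median of 10000 lists of other genes matched on mean level was 0.043. Medians were 0.14 on day 1 and 0.27 on day 2, and camera with an estimated correlation gave an unadjusted p of 0.0059. The maltose transporter genes MAL11 (2.58 ± 0.15) and MAL31 (2.35 ± 0.20), the glutathione transferase gene GTT2 (2.09 ± 0.16) and AAD4, an aryl alcohol dehydrogenase gene (2.07 ± 0.13, and 1.03 in a dimmer probe set), rose most besides DAL5. The hydroperoxidase gene HYR1 fell by 1.21 ± 0.16. Of the 190 genes 32 belong to the lists described above, and probe sets of end families are shared between near-identical genes. Genes already seen to rise, among them MAL11, MAL31, DAL5 and seripauperin genes, are members, so the tests of this group are not independent support. Weaker silencing near chromosome ends may be 1 source of this shift, with the median of 0.20 as the tested value, but silencing itself was not measured.

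It was asked whether falling mitochondrial transcripts went with the retrograde response, which links mitochondrial state to nuclear genes. Its 8 genes had a median of 0.02, with medians of -0.28 on day 1 and 0.32 on day 2. Only ATO3, an ammonium transporter gene, passed, and it rose by 0.56 ± 0.15 (adjusted p = 0.0276). CIT2 and DLD3 differed by 0.24 ± 0.36 and -0.24 ± 0.31 without passing. Camera gave an unadjusted p of 0.466 for the list, which leaves the question undecided, and 6 of the 8 genes stand in other lists. Drug resistance genes, targets of Pdr1 and Pdr3, had a median of 0.19 over 10 genes and an unadjusted p of 0.171 in camera, undecided as well. Of these the transporter gene PDR5 rose by 0.45 ± 0.13 and ICT1 fell by 0.64 ± 0.18.

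Probe sets without a single gene name gave 302 calls among 2771, and 264 of these, or 87.4%, were upward. The 92 tRNA probe sets had a median of 0.26. Groups did not overlap in 2107 probe sets, 22.7% against 2.86% by chance. Between the hybridization days 1194 probe sets differed when the day was fitted as a block, and the day cannot be told apart from the replicate strains.

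The 8 arrays can be parted into 4 and 4 in 35 ways. Of these 1, the real one, called as many as 1628 probe sets, and the highest other count was 35, from the grouping by hybridization day. A share of 1 in 35 is the smallest possible and argues against chance for that count. Groupings that mix the groups carry any group difference as error, which lowers their counts. The count does not tell V81G from other differences shared by a group's strains. For the NMD substrates 3 of the 35 gave a list p as small as the real 2.9e-06, with 1.4e-07 as the smallest other, so chance cannot be excluded for that list at the preset correlation. For the number of lists 1 of the 35 gave as many as the real 20, and the highest other was 19, a margin of 1 list, which is too narrow to set that number apart from chance. The 8 groupings that part all 4 same-numbered pairs, as the real one does, are too few for a share under 0.05. Among them the real one called 1628 probe sets against at most 1, 20 lists against at most 19, and gave an NMD p of 2.9e-06 against 9.9e-07.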
